A study of Mus musculus with 2 samples.

How the data were processed

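The series holds single-cell RNA sequencing of OT-I CD8 T cells, which carry a transgenic T cell receptor for a peptide of ovalbumin. Cells of either genotype, WT or PSGL-1-/- (deletion of Selplg, which encodes the adhesion molecule PSGL-1), were activated in vitro and transferred into separate hosts with B16-OVA melanoma, an ovalbumin-expressing tumour line. Donor cells were sorted by CD90.1 or CD45.1 at 6 days after transfer; the labels do not say which marker went with which genotype. Mice were pooled before sorting, so each group is 1 library (10x Genomics 3' v2 chemistry).

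The deposited matrices hold raw UMI counts per gene and cell barcode, whole numbers with no normalization, for barcodes called as cells. The submitters' processing notes name Cell Ranger 2.2.0, Seurat 4.1.1 and the mouse build mm10; counting settings were not stated. Each library came with 2 copies of its matrix, with 0 entries that differed, and 1 copy was used. The WT library held 10499 barcodes and 38856673 UMIs, and the PSGL-1-/- library 2941 barcodes and 24259061 UMIs. In the deposited run metrics, sequencing saturation was 34.4% in the WT library and 61.9% in the PSGL-1-/- library. Gene symbols and identifiers are those of the files. Positions and transcript lengths come from GENCODE M21 and were found for 27645 of 27998 gene identifiers. The length of a gene is the median over its APPRIS principal transcripts, a measure chosen after 4 measures had been compared on these data with nearly equal outcome.

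Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept. Doublets were called with scrublet, through scanpy, in each library. It called 0 of 10315 WT barcodes and 2 of 2919 PSGL-1-/- barcodes, which is too few for a working threshold, so doublets remain in the data. Cells of both libraries were clustered together without integration: counts scaled to 10000 per cell and log transformed, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 0.6. Selplg, sex-linked, antigen receptor variable, ribosomal protein and mitochondrial genes were kept out of the features. A cluster took the name of a cell class, as class-like, when at least 3 of its top 10 genes were among that class's fixed markers, and more than among those of any other class. Clusters of cell types other than T cells were left out, which gave 10303 WT and 2897 PSGL-1-/- T cells.

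Counts were summed over the T cells of a library and scaled by the library's total to CPM. The log2 ratio of PSGL-1-/- over WT used a pseudocount of 1 CPM in both. CPM have exact Poisson 95% intervals and shares of cells have exact Clopper-Pearson 95% intervals. The interval of a ratio is the exact conditional binomial interval of the 2 counts and holds for the ratio without the pseudocount. All of these cover counting error only. With 1 library per group there is no replicate, so no test was run, no p-value was computed and no gene was called changed: differences are described by size, as the number of genes with a 2-fold or larger ratio among those at 20 CPM or more in either library. Differences between libraries have no replicate check.

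26 gene lists were fixed, of T cell programmes, general programmes and markers of other cell types. A list's result is the median log2 ratio of its members at 10 CPM or more in either library, with an order-statistic 95% interval over members, and its percentile among 10000 random lists of equal size matched on expression in 20 bins. The percentile describes these libraries alone. Genes named in the text are Selplg, the 12 highest and 12 lowest ratios among genes at 50 CPM or more, the 3 members of each list with the largest ratio in either direction, and a set of 14 genes for shares of cells. From the 12 highest and lowest, Selplg, sex-linked, antigen receptor variable, ribosomal protein, mitochondrial, haemoglobin and other-cell-type genes and names of the Gm and Rik kinds were left out by name pattern or list. The pattern for ribosomal proteins asks for a digit after Rps or Rpl, so Rplp0 was not left out and is not in that list. For shares, every cell was thinned to 1400 UMIs, the 10th percentile in the shallower library; 873 WT cells and 0 PSGL-1-/- cells were shallower and were left out. Thinning equalizes UMIs per cell and leaves the difference in saturation. Ratios were also computed inside each cluster with at least 100 cells of each library. Clusters at equal weight, in the main clustering, are the mean of the log2 ratios over these 5 clusters. The T cell clusters left out held 2392, 1939 and 276 WT cells and 36, 49 and 92 PSGL-1-/- cells. A cluster of 124 WT and 1732 PSGL-1-/- cells counts as much as any other.

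The groups, gene lists, markers, filters, rule for named genes and most alternatives were set before the data were examined. Those alternatives were scaling by the median of ratios or by trimmed mean of M values (TMM), both computed directly; the mean over cells; all barcodes; a stricter filter of 1000 genes and 5% mitochondrial UMIs; doublets kept; thinned cells; clusters at equal weight; other minimum CPM and a pseudocount of 10 CPM; and other clustering settings. Chosen after seeing the data were the removal of a lowess curve of the ratio over log2 transcript length (span 0.05), the removal of the highest doublet scores at 0.8% per 1000 barcodes (851 WT and 68 PSGL-1-/- barcodes), clustering without transcripts under 1000 nt, 5 further thinning seeds for the clustering, equal weight of the clusters of thinned cells for the stem and memory list, and a list of p53 target genes.

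The calculation was tested on simulated data after it had first been run on the real libraries. The simulated counts were Poisson draws from 1 mean profile at the 2 library totals, with no variation between cells, mice or libraries. They check the calculation and give no rate of false differences between real libraries. Among 4226 simulated genes with no difference, 0 reached 2-fold. The 95% intervals held the simulated ratio for 95.4% of 4426 genes. Of 50 genes simulated at a log2 change of 1, before scaling by the total, 12% reached 2-fold, and of 50 at -1, 66% did. The simulated changes alter the total and so shift every CPM ratio, and the pseudocount draws ratios toward 0, which can set these shares apart. A count at 2-fold misses genes near that size. Genes simulated at 2 or -2 all reached it. Of 100 lists with no difference, 7 fell under percentile 5 or over 95. Software was Python 3.11.15 with scanpy 1.11.5, igraph 0.11.9, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.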

Results

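The data are 2 single-cell libraries of OT-I CD8 T cells recovered from B16-OVA melanoma 6 days after transfer, 1 of WT cells and 1 of PSGL-1-/- cells, each from pooled mice. The retained T cells were 10303 WT cells with 38615017 UMIs, a median of 3458 per cell, and 2897 PSGL-1-/- cells with 24028426 UMIs, a median of 7586 per cell. The comparison asks how the transcriptome of tumour-infiltrating CD8 T cells differs when they lack PSGL-1. With 1 library per genotype, differences are given as sizes with counting error and have no replicate check. Where a level is given against another, the PSGL-1-/- level comes first and the WT level second.

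Selplg (ENSMUSG00000048163, mm10 chromosome 5, 113818536 to 113832644), the deleted gene, was lower in PSGL-1-/- T cells, at 9.86% of the WT level. Its level was 457 CPM (451 to 464) in the WT library, from 17663 UMIs, and 45.1 CPM (42.5 to 47.9) in the PSGL-1-/- library, from 1084 UMIs, a log2 ratio of -3.31 with the pseudocount. After thinning to 1400 UMIs per cell, which left out 873 shallower WT cells, 45.9% of WT cells (44.9 to 46.9) and 8.22% of PSGL-1-/- cells (7.24 to 9.28) had a Selplg UMI; without thinning the shares were 73.4% and 30.1%. At least 3 Selplg UMIs were found in 26.9% of WT cells and 0.759% of PSGL-1-/- cells.

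Genes of the stem and memory programme were lower in the PSGL-1-/- T cells. Tcf7, which encodes TCF-1, the transcription factor of stem-like and memory T cells, was at 19.8 CPM (18.4 to 21.2) in WT and 6.91 CPM (5.90 to 8.04) in PSGL-1-/- cells. The lymph node homing gene Ccr7 was at 18.7 CPM in WT cells and 7.49 CPM in PSGL-1-/- cells. Emb, an immunoglobulin family adhesion molecule, was at 30.9 against 70.3 CPM. Of the 21 measured members of the fixed stem and memory list, 20 were lower and 1 was higher, with 19 lower when scaled by the median of ratios. These counts stand against a background in which most genes were lower, with a median of -0.19 over all genes. The list median was -0.56 (-0.71 to -0.27), below that of each of the 10000 matched random lists. With clusters at equal weight it was -0.31 (-0.56 to -0.10), against a median of -0.20 for all genes, and the ratios of Tcf7 and Ccr7 were -0.71 and -0.65 instead of -1.39 and -1.21. This weighting leaves out the clusters of 2392 and 1939 WT cells, which had 36 and 49 PSGL-1-/- cells. Under the stricter cell filter the list median was -0.44 (-0.64 to -0.18), an interval that also holds the median of all genes, -0.20.

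Targets of T cell receptor signalling lay low among random lists, at percentile 0.31, although the interval of the list median, -0.32 (-0.57 to -0.15), holds the median of all genes. Of the 29 members, 23 were lower, or 21 when scaled by the median of ratios. Most genes were lower as well. The upper quartile of all genes was -0.13 for transcripts of 1000 to 2000 nt and 0.0089 for those of 2000 to 5000 nt. The count of lower members alone therefore shows no shift of the list. With clusters at equal weight the list median was -0.25 (-0.36 to -0.034), against -0.20 for all genes, and after removal of the length trend, chosen after seeing the data, it was -0.14 (-0.35 to 0.042), against 0.00. The immediate early transcription factors Nr4a1 and Egr2 were at 45.9 and 15.2 CPM in WT cells and at 25.3 and 8.49 CPM in PSGL-1-/- cells; with clusters at equal weight the ratio of Nr4a1 was -0.24 instead of -0.83. The stress-induced gene Gadd45b was at 25.2 against 41.8 CPM. The genes of the receptor complex and its kinases had a median of -0.09 (-0.22 to 0.07), at percentile 93.5; Lat, the adaptor of the receptor, was at 297 against 425 CPM, Cd8a at 502 against 711 CPM and Cd3g at 1636 against 2092 CPM.

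Inhibitory receptor and exhaustion genes did not move together. The median of their 24 measured members was -0.12 (-0.40 to 0.05), at percentile 83.4, but -0.19 at percentile 34.1 with cells thinned and -0.27 with clusters at equal weight, against -0.18 and -0.20 for all genes. Inside clusters the list lay below all genes only in the cluster of 124 WT and 1732 PSGL-1-/- cells, at -0.45 against -0.14. Tox, the transcription factor of exhausted T cells, was higher in PSGL-1-/- cells, at 58.9 CPM (55.9 to 62.0) against 34.2 CPM (32.4 to 36.1), and Cd160, an inhibitory receptor, was lower, at 200 against 348 CPM. Pdcd1, which encodes PD-1, was at 180 CPM in WT and 187 CPM in PSGL-1-/- cells, with overlapping intervals. Its ratio of 0.049 lay above the median of all genes, -0.19. It was -0.026 with thinned cells and 0.25 after removal of the length trend. Cytotoxic and effector genes had a median of -0.11 (-0.33 to 0.04), at percentile 78.4. Gzmb (granzyme B) was at 2102 against 2441 CPM and Ifng (interferon gamma) at 688 against 765 CPM. Their ratios of -0.22 and -0.15 lay near the median of all genes, -0.19. Both were higher after removal of the length trend, at 0.060 and 0.19, and Ifng was at 0.22 under the stricter cell filter. Gzmm was lower, at 6.37 against 14.7 CPM (a ratio of -1.09, or -0.44 with clusters at equal weight), as was Srgn, the granule proteoglycan serglycin, at 790 against 1239 CPM. Gzmf was higher, at 60.8 against 30.9 CPM, although not with clusters at equal weight, where its ratio was -0.0089.

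Glycolysis genes lay high among random lists, at percentile 99.5, with a median of 0.04 (-0.13 to 0.35) and 11 of 21 members higher. The enzymes Pgk1 (80.8 against 31.1 CPM) and Hk2 (a ratio of 0.91) and the hypoxia-induced Higd1a (403 against 261 CPM) were higher in PSGL-1-/- cells. With cells thinned the list stood at percentile 83.0 with a median of -0.08. Among residency genes, with a median of 0.01 (-0.28 to 0.19) at percentile 98.5, the transcription factor Runx3 was at 141 CPM (136 to 146) in PSGL-1-/- and 69.6 CPM (67.0 to 72.3) in WT cells; Itgb7 (46.1 against 73.1 CPM) and Cd69 (106 against 143 CPM) were lower. With clusters at equal weight the residency median was -0.25. Inside clusters the residency list lay below all genes only in the cluster of 124 WT and 1732 PSGL-1-/- cells, at -0.58 against -0.14. Migration and adhesion genes had a median of -0.05 (-0.31 to 0.16), at percentile 98.1. Cytokine receptors had a median of -0.06 (-0.20 to 0.11), at percentile 93.7, with the interleukin 2 receptor chain Il2ra and the tumour necrosis factor receptor Tnfrsf1a lower, at 36.0 against 59.2 CPM and 9.78 against 15.2 CPM, and the common gamma chain Il2rg higher, at 175 against 124 CPM.

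The medians of the cell cycle, interferon and stress lists had intervals that held the median of all genes, except S phase under the stricter cell filter, at -0.31 (-0.42 to -0.22) against -0.20. S phase genes had a median of -0.22 (-0.32 to -0.12), at percentile 27.8, or 6.45 with cells thinned and 1.75 after removal of the length trend, with Hells higher (94.7 against 52.2 CPM) and the nucleotide synthesis gene Tyms (114 against 171 CPM) lower. G2 and M phase genes had a median of -0.18 (-0.25 to -0.12), at percentile 52.4, with Cdca2, Aurkb and Smc4 farthest from 0 at -0.52, -0.47 and -0.44. Interferon response genes had a median of -0.18 (-0.29 to -0.08), at percentile 53.8; Ifi27l2a was at 2298 against 996 CPM, with a ratio of 1.21 that was 0.13 after removal of the length trend, Socs1 at 25.8 against 41.7 CPM (a ratio of -0.67, or -0.20 with clusters at equal weight) and Igtp at 70.6 against 102 CPM. Apoptosis and survival genes had a median of -0.13 (-0.27 to 0.02), at percentile 77.2, but -0.17 at percentile 48.7 with cells thinned and -0.26 (-0.37 to -0.041) with clusters at equal weight, with the cell cycle inhibitor Cdkn1a (24.7 against 72.7 CPM), the death receptor Fas (10.2 against 17.7 CPM) and Bax (264 against 428 CPM) lower. Genes induced by cell dissociation had a median of -0.23 (-0.36 to 0.00), at percentile 29.6, with Btg2 at 0.63, Dnaja1 at -0.55 and Hspa1a at 1.26, or -0.89 with clusters at equal weight. The unfolded protein response had a median of -0.14 (-0.26 to 0.01), at percentile 72.5, with Pdia4 at 0.39, Xbp1 at -0.36 and Ddit3 at -0.36, or -0.78 with clusters at equal weight.

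In all, 121 of 4643 genes at 20 CPM or more were at least 2-fold higher in PSGL-1-/- T cells and 16 at least 2-fold lower. The median over all genes was -0.19, and the list medians are read against it through the random lists; scaling by the median of ratios or by TMM shifted it by 0.13 and 0.14, which turns the sign of the medians of the cytotoxic, inhibitory, receptor complex, cytokine receptor and migration lists. Under the stricter cell filter the cytotoxic, receptor complex and residency lists lay above the median of all genes with intervals apart, at 0.014, -0.032 and 0.076. The genes higher in PSGL-1-/- cells had short transcripts. Genes with transcripts under 400 nt had a median ratio of 1.74 (21 genes), those of 400 to 500 nt 1.11 (48 genes), those of 500 to 600 nt 0.60 (69 genes) and those of 800 to 1000 nt -0.32 (263 genes). Of the 121 genes, 91 were under 1000 nt, as were 13.3% of the 4638 genes with a known length, and 44 had ribosomal protein or Gm-type names.

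**Figure D1:**
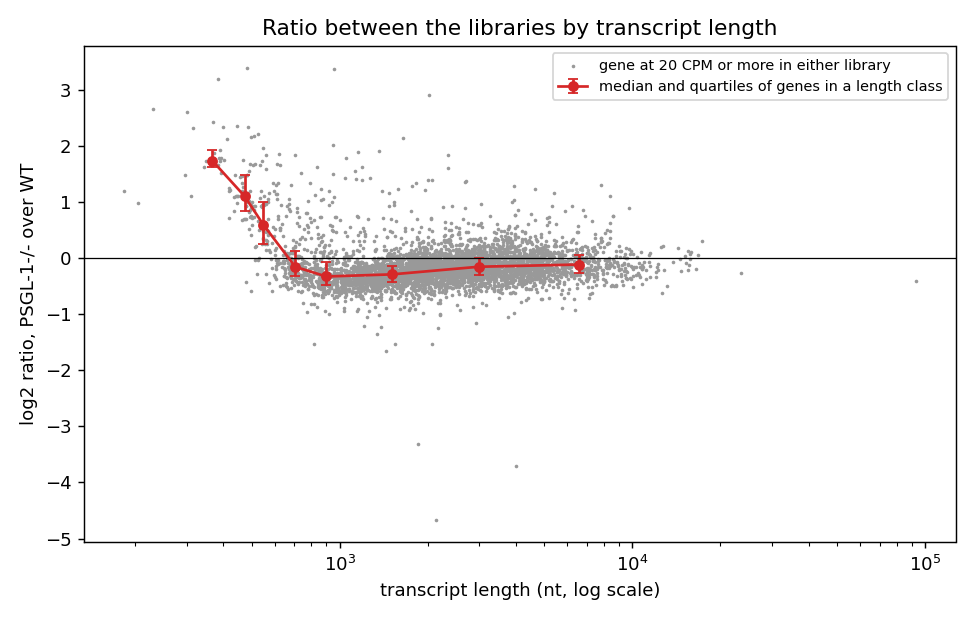
Log2 ratio of PSGL-1-/- over WT for each gene at 20 CPM or more, against transcript length in nt on a log axis; red points are medians of length classes and bars their quartiles. The median lies at 1.74 under 400 nt and at -0.15 from 600 to 800 nt.

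Lists with many short transcripts lay high. Oxidative phosphorylation genes, which encode the respiratory chain, had a median of 0.42 (-0.12 to 0.66), above each random list, and 10 of 51 members were at least 2-fold higher. Atp5k was at 494 against 133 CPM, Atp5e at 1122 against 480 CPM and Ndufv3, whose transcript has 1582 nt, at 378 against 160 CPM, with a ratio of 1.24 that was not lower after removal of the length trend. Ribosomal protein genes had a median of 0.31 (0.09 to 0.53), also above each random list, led by the pseudogene-type Rps26-ps1, Rpl36-ps3 and Rpl27-ps3 with ratios of 2.33, 2.33 and 2.13, or 0.79, 0.092 and 0.67 after removal of the length trend. Genes of the mitochondrial genome had a median of -0.16 (-0.31 to 0.99), at percentile 56.8, and their short members mt-Nd3, mt-Nd4l and mt-Atp8 had ratios of 1.74, 1.48 and 0.99. After removal of the length trend, chosen after seeing the data, the median of the oxidative phosphorylation list was 0.05, at percentile 80.0, that of the ribosomal protein list 0.18, still above each random list, and that of the stem and memory list -0.37 (-0.60 to -0.12), still below each random list. The ratio of Tox was then 0.87, that of Runx3 1.11 and that of Atp5k 0.11. Those of mt-Nd3, mt-Nd4l, mt-Atp8 and Atp5e turned negative. The curve was fitted on these genes too. Of 138 genes under 600 nt, 72 lay outside the ribosomal, respiratory, mitochondrial and pseudogene-type groups. Part of the fall of the short members toward 0 is therefore built in.

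**Figure D2:**
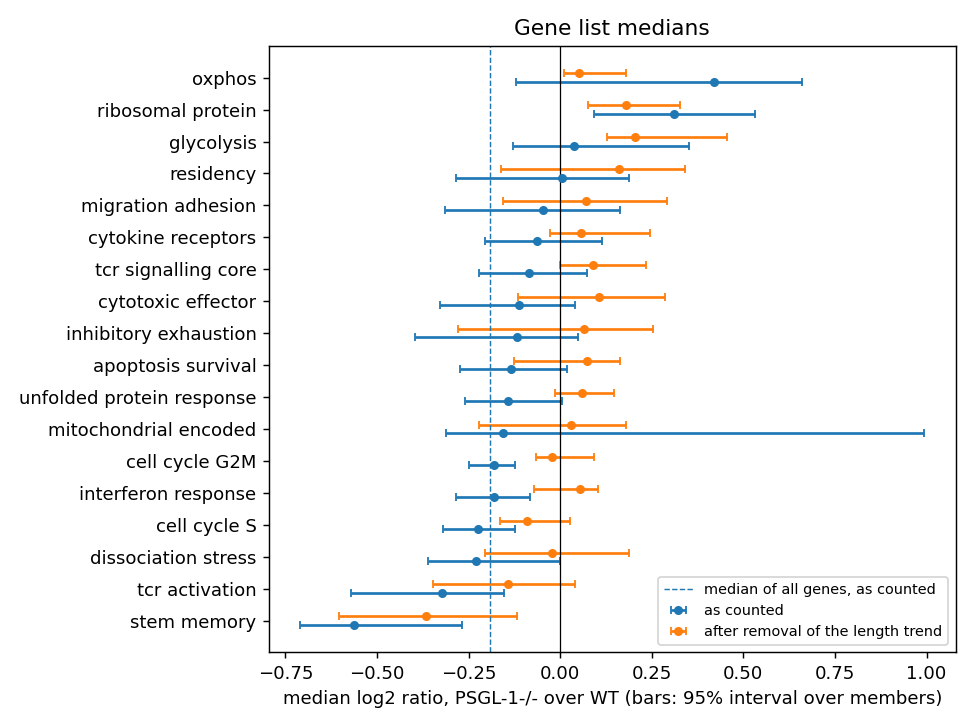
Median log2 ratio of PSGL-1-/- over WT for each gene list set before the data were examined and with at least 6 measured members, as counted (blue) and after removal of the length trend (orange), with 95% intervals over members. The stem and memory list is the lowest of those shown in both, at -0.56 and -0.37.

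Among genes at 50 CPM or more, the lowest ratio was that of Ctse (ENSMUSG00000004552, chromosome 1, 131638306 to 131675505), which encodes the aspartic protease cathepsin E. It had 31 UMIs in PSGL-1-/- and 2204 in WT T cells, 1.29 CPM (0.877 to 1.83) against 57.1 CPM (54.7 to 59.5), a log2 ratio without pseudocount of -5.47 (-6.03 to -4.96). It lies 6.42 Mb from Ptprc, which encodes CD45, a marker named for the sorting. The others of the 12 lowest were Cdkn1a, Hmgn1, Emb, Rplp0, Rgcc, Serpine2, Erdr1, Pdlim1, Ubash3b, Serpina3g and Thy1, with levels, pseudocount added, 1.84- to 2.87-fold higher in WT cells. Hmgn1, a nucleosome-binding protein, was at 48.4 against 115 CPM, and Thy1, which encodes CD90, at 390 against 720 CPM. The ribosomal protein gene Rplp0 was at 3842 against 7727 CPM, while Rplp0 together with its pseudogene-type model Gm8730, added after its values were seen, was at 8262 against 8150 CPM. The 12 highest included Hist1h2ap, Mt2, Polr2l, Mt1, Usp50, Atp5k, Txk, Snrpg, Lsm7, Ndufa3 and Tmsb10, with levels, pseudocount added, 3.19- to 10.5-fold higher in PSGL-1-/- cells. Of the 12, 8 had transcripts under 1000 nt. The histone gene Hist1h2ap was at 915 against 86.5 CPM, with a ratio of 3.39, or 2.44 after removal of the length trend. The metallothioneins Mt1 and Mt2, which bind zinc, were at 550 against 140 CPM and 237 against 51.5 CPM, and after removal of the length trend had ratios of 1.45 and 1.42; with clusters at equal weight these were 1.11 and 1.18 instead of 1.97 and 2.18. The ratios of Hmgn1 and Emb were then -0.68 and -0.56 instead of -1.23 and -1.16. Txk, a kinase of the Tec family, was at 75.3 against 20.1 CPM.

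Shares of T cells with a UMI, after thinning to 1400 UMIs per cell, gave the same order as the summed counts for Tcf7 and Tox, with intervals apart here and under the stricter cell filter. Without thinning, where the deeper PSGL-1-/- library gains, Tcf7 was still lower, at 5.88% in WT and 3.97% in PSGL-1-/- cells, with intervals apart. For Tox that setting (11.0% and 32.1%) cannot tell the order from the difference in depth. A Tcf7 UMI was found in 2.98% of WT cells (2.65 to 3.34) and 1.38% of PSGL-1-/- cells (0.988 to 1.88), and a Tox UMI in 4.60% (4.19 to 5.04) and 7.21% (6.30 to 8.22). Slamf6, a surface marker of stem-like cells, was found in 3.01% (2.68 to 3.38) and 1.69% (1.25 to 2.23), Entpd1, which encodes the ectonucleotidase CD39, in 1.35% (1.12 to 1.60) and 2.42% (1.89 to 3.04), and Gzma in 19.5% (18.7 to 20.3) and 23.0% (21.4 to 24.5). Under the stricter cell filter the intervals of Slamf6 (2.55% and 2.11%), Entpd1 (1.49% and 2.18%) and Gzma (18.8% and 20.8%) overlapped. Those of Gzma also overlapped with fewer UMIs per cell and all 10303 WT cells kept (15.3% and 16.3%), and its ratio over summed counts was 0.040, or 0.65 with thinned cells and 0.29 with clusters at equal weight, with 4 of 5 clusters higher. Of the 276 WT cells of the Effector-like cluster, which is high in Gzma and in Klf2 (1131 CPM in its WT cells), 70 had enough UMIs to be counted after thinning. All 92 PSGL-1-/- cells of that cluster were counted. The ratio of Entpd1 over summed counts was 0.75, and it was higher in PSGL-1-/- cells in 5 of 5 clusters. Without thinning the order of Slamf6 reversed, with the PSGL-1-/- share 1.04 percentage points higher, as did its ratio over summed counts, from -0.78 to 0.11, with clusters at equal weight. The shares of Pdcd1 (20.7% and 21.1%), Havcr2 (6.62% and 6.83%), Ifng (27.8% and 26.2%), Mki67 (6.81% and 6.04%) and Klf2 (5.46% and 5.32%) had overlapping intervals. Those of Havcr2 were apart under the stricter cell filter, at 6.01% and 7.77%, and those of Ifng with fewer UMIs per cell, at 18.4% and 16.1%. Over summed counts, Havcr2 turned from 0.23 to -0.034 with clusters at equal weight and Klf2 from -0.56 to 0.39 with thinned cells, and no order is read from Il7r, Gzmb or Cxcr6, whose shares went against their summed counts. The part of free RNA in these shares was not measured, and Selplg, the deleted gene, was found in 8.22% of PSGL-1-/- cells.

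**Figure D3:**
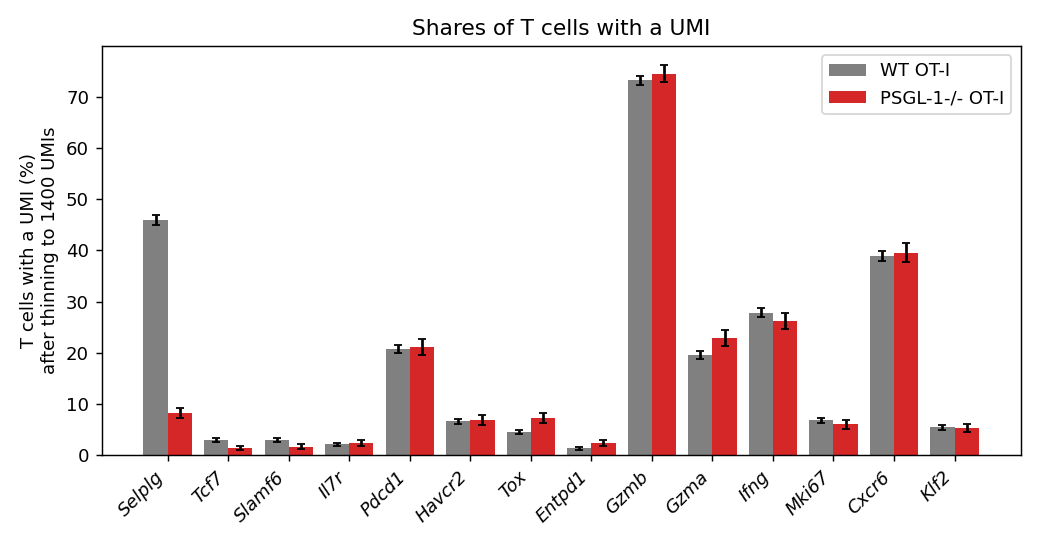
Share of T cells with at least 1 UMI of each gene shown in the WT (grey) and PSGL-1-/- (red) libraries, in percent after thinning to 1400 UMIs per cell, with exact 95% binomial intervals. Tcf7 was found in 2.98% and 1.38% of cells and Tox in 4.60% and 7.21%.

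Joint clustering of cells as sequenced separated them in large part by library: in the largest PSGL-1-/- cluster 93.3% of cells were PSGL-1-/-, and its top genes included Hist1h2ap, Mt1, Mt2 and pseudogene-type names. With cells thinned before clustering, by the seed set in advance or 5 added ones, the highest PSGL-1-/- part of a cluster of 500 or more cells was 34.4% to 38.8%. The cycling and interferon-stimulated clusters of the main clustering were also split by library, so their sizes are not compared. An Effector-like cluster, with Gzma and Klrg1, a marker of terminal effector cells, among its top genes, held 2.68% of WT cells (2.37 to 3.01, 276 cells) and 3.15% of PSGL-1-/- cells (2.55 to 3.85, 92 cells); under the stricter cell filter the shares were 0.108% and 1.54%, and the WT cells in it had a median of 1177 UMIs. A stem- or memory-like cluster was not found in the main clustering and was found in 6 of 14 clusterings, where the 14 include 5 with thinning seeds added after seeing the data. In 5 of the 6 its share was higher in WT cells with intervals apart, 5.97% to 19.8% in the WT and 4.49% to 9.50% in the PSGL-1-/- library. Of these, 3 came from the added thinning seeds, at 12.5% to 19.8% and 6.79% to 9.50%, while the seed set in advance gave no such cluster. The other 2 used cells as sequenced and were split by library, with a cluster 94.4% or 94.3% PSGL-1-/-, so no order is read from them. Keeping the 2 called doublets was enough to give a cluster of this name with 18.3% of WT cells, so the label is unstable. In the clustering without cell cycle genes the shares were 2.12% (1.85 to 2.42) and 2.06% (1.57 to 2.64), which overlap.

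Inside clusters, the stem and memory list had its median below that of all genes in 4 of 5 clusters with at least 100 cells of each library. Its medians ranged from -0.51 to -0.11, and from -0.34 below to 0.13 above all genes of the same cluster. The margin was small in the cluster of 1355 WT and 168 PSGL-1-/- cells, at -0.28 against -0.22. It was also small in that of 124 WT and 1732 PSGL-1-/- cells, at -0.21 against -0.14. The T cell receptor target list was below in 2 of the 5 clusters, the exhaustion, cytotoxic, residency, migration and cytokine receptor lists in 1 of 5 each, and the glycolysis, oxidative phosphorylation, ribosomal protein, mitochondrial and receptor complex lists in 0 of 5. The smallest excess over all genes was 0.57 for oxidative phosphorylation and 0.41 for ribosomal protein genes. It was close to 0 for glycolysis (0.015), mitochondrial (0.0072) and receptor complex genes (0.0067). The S phase, G2 and M phase and dissociation lists were below in 3 of 5, and the interferon, apoptosis and unfolded protein lists in 2 of 5. Tcf7 and Ccr7 were lower in PSGL-1-/- cells in 4 of the clusters, Cdkn1a and Ctse in 5.

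Markers of other cell types were few in the retained T cells. The summed level of the myeloid markers was 462 CPM (456 to 469) in WT and 562 CPM (552 to 571) in PSGL-1-/- cells, and 3 of the 16 genes reached 10 CPM, with Fcer1g at 284 against 159 CPM (a ratio of 0.84, or 0.15 with clusters at equal weight), Cst3 at 238 against 267 CPM and Cd68 at 8.78 against 11.0 CPM; Cst3 and Cd68 turned higher after removal of the length trend, at 0.14 and 0.054, and Cd68 also with thinned cells, at 0.080. Sums for B cell (5.67 and 2.58 CPM), NK cell (3.86 and 2.87 CPM), CD4 T cell (31.9 and 26.4 CPM), melanoma (8.24 and 10.8 CPM) and stromal markers (18.2 and 16.4 CPM) were lower still, and 2 erythroid UMIs were found in each library. The most abundant CD4 T cell marker was Izumo1r, at 15.7 against 26.0 CPM, and the most abundant stromal marker Pecam1, at 16.2 against 18.0 CPM. Sex-linked genes summed to 755 CPM in WT and 861 CPM in PSGL-1-/- cells, with Xist at 739 and 836 CPM and Tsix at 16.4 and 24.9 CPM.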

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

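The tests of an explanation in this part were chosen only after the results were seen; thinning and equal weight of clusters were among the alternatives set before the data were examined. Myeloid-like barcodes, left out of the T cell comparison, made up 0.686% of the retained PSGL-1-/- barcodes (0.419 to 1.06, 20 barcodes) and 0.116% of the retained WT barcodes (0.0601 to 0.203, 12 barcodes). They are given here because they are a signal in barcodes that the comparison does not use, and no test was made of their number. They also held Cd3d, at 1189 CPM in the PSGL-1-/- and 1719 CPM in the WT library.

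Genes with transcripts under 600 nt were higher in the PSGL-1-/- library, with a median ratio of 0.99. With all cells thinned the median was 0.987 (0.869 to 1.11). Random draws keep the proportions within a cell, so thinning could move it only through the weight of cells and the shallow WT cells left out. Depth per cell is therefore not decided by thinning. The tables argue against the mix of clusters, among those with at least 100 cells of each library, since the median stayed at 0.977 (0.846 to 1.08) with these at equal weight. The tables also argue against higher ribosomal and respiratory chain transcription as the whole cause. Of those lists, 39 members with transcripts of 1000 nt or more differed from other genes of that length by -0.023 (-0.18 to 0.18). The ribosomal list follows a name pattern, so not all of the 39 need be ribosomal proteins, and shorter members are not covered. After removal of the length trend the ribosomal protein list still lay above each random list, so a part of that kind stays open. A candidate explanation is a difference between the libraries in the recovery of short transcripts, since 72 genes under 600 nt outside the ribosomal, respiratory and pseudogene-type groups lay 1.05 (0.90 to 1.18) above all genes. Genotype and library are the same split here, so an effect of genotype on short transcripts stays open and untested.

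The stem and memory list was lower in the PSGL-1-/- library, with a median of -0.56 (-0.71 to -0.27). The tables argue against the length trend as the whole cause, since the median was -0.37 (-0.60 to -0.12) once that trend was removed, against 0.00 for all genes. With thinned cells the median was -0.53 (-0.69 to -0.27), against -0.18 for all genes. Thinning could move it only through the weight of cells and the shallow WT cells left out, so depth per cell is not decided. A different mix of cell states may account for part of the lower list median. With clusters of at least 100 cells of each library at equal weight, it was -0.31 (-0.56 to -0.10), and the interval holds both the median of all genes, -0.20, and the value as counted. With clusters found with thinned cells, which split less by library, it was -0.48 to -0.37, the highest at -0.37 (-0.68 to -0.15) against -0.20 for all genes, and 3 of 6 intervals lay below the median of all genes, so a smaller pool of stem-like cells and a lower level within cells cannot be told apart. An effect of genotype stays open and untested, as does a difference between the pools of mice.

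Selplg UMIs remained in the PSGL-1-/- library, at 9.86% of the WT level. WT donor cells or their RNA are not the whole source, since Ctse, at 2.26% of its WT level, allows at most 32.6% of the Selplg that was counted. Free RNA at a fixed amount per droplet stays open: Selplg UMIs per cell were 1.98-fold higher (1.47 to 2.69) in the deepest 10% of PSGL-1-/- cells than in the shallowest 10%, between no difference and the 4.22-fold of WT cells, while depth differed 6.17-fold. Selplg in the shallowest 10% was at 90.0 CPM and in the deepest at 27.0 CPM. Transcripts from parts of the gene left in place by the deletion and RNA of host cells were not tested.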

How the results depend on the processing

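Removal of the length trend, removal of the highest doublet scores, clustering without short transcripts, further thinning seeds and equal weight of clusters of thinned cells were chosen only after the results were seen. The Selplg level stayed lower in PSGL-1-/- cells under all 10 alternatives, with log2 ratios of -3.33 to -2.87; it moved beyond counting error to -3.18 with the median of ratios, -3.17 with TMM, -3.11 as a mean over cells, -2.87 with thinned cells and -3.09 without the length trend. The number of genes at least 2-fold higher was 191 with no filter on low genes. The number lower was 50 with no filter, 6 at 50 CPM and 8 with a pseudocount of 10 CPM, and these 4 counts follow from how many low genes each setting admits or shrinks. The other 22 of 26 alternative counts were within 1.5 times the main ones. Of 258 alternative list medians, 241 kept to their intervals, with the stem and memory list lower in each. Removal of the length trend gave 0.10 for the cytotoxic, 0.065 for the inhibitory, -0.14 for the T cell receptor target, 0.090 for the receptor complex, -0.089 for the S phase, -0.022 for the G2 and M phase, 0.074 for the apoptosis and 0.061 for the unfolded protein list, and turned the interferon list to 0.053. Scaling by the median of ratios and TMM gave -0.11 and -0.10 for S phase, -0.047 and -0.039 for G2 and M phase, and -0.051 and -0.043 for interferon genes, which is the shift of all genes. G2 and M phase genes were at -0.28 under the stricter cell filter and -0.10 at equal cluster weight; the cause was not tested. Of 940 alternative ratios of named genes, 565 kept to the interval of counting error and 353 moved beyond it in the same direction or without a clear one. The other 22 reversed. Without the length trend these were Cd3g at 0.024, Gzmb at 0.060, Ifng at 0.19, Cxcr6 at 0.16, Cst3 at 0.14, Cd68 at 0.054, Atp5e at -0.16, mt-Nd3 at -0.22, mt-Nd4l at -0.92 and mt-Atp8 at -2.47, which follows from the curve. At equal cluster weight they were Gzmf at -0.0089, Hspa1a at -0.89, Slamf6 at 0.11 and Havcr2 at -0.034, with thinned cells Klf2 at 0.39, Cd68 at 0.080, Trp53inp1 at 0.038 and Cxcr6 at 0.034, and under the stricter filter Ifng at 0.22 and Cxcr6 at 0.0051; the cause of these was not tested. Cxcr6 was at 0.087 and 0.095 with the median of ratios and TMM, within the shift of all genes. The Effector-like share of WT cells was 0.108% under the stricter cell filter, 0.371% with thinned cells and 2.16% without short transcripts, and that of PSGL-1-/- cells 1.54% under the stricter filter; the stricter filter and thinning leave out shallow cells. Myeloid-like shares with thinned cells were 0.0318% and 0.377%. The Slamf6 share reversed to 1.04 percentage points higher in PSGL-1-/- cells without thinning, where the deeper library gains. Inside clusters, the stem and memory list was below all genes in 100% of clusters at resolution 0.3 and in 100% at 1.0. With a minimum of 30 cells it was below in 6 of 8 clusters and above in 2. The inhibitory and residency lists were below in 0% at 0.3, and the cytokine receptor list in 0% at 1.0, with 3 clusters at 0.3. The glycolysis list was below in 1 of 3 clusters at 0.3 and 2 of 4 at 1.0. The receptor complex list was below in 1 of 4 at 1.0, and the mitochondrial list in 2 of 8 with a minimum of 30 cells. Depth limits genes with few UMIs: the interval of Tnfrsf1a ran from -0.86 to -0.42 and that of Selplg from -3.43 to -3.25.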

Other observations

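The p53 target list and the genes of this part were chosen only after the results were seen. Several targets of p53, the transcription factor of the DNA damage response, were lower in PSGL-1-/- T cells. Phlda3 was at 6.62 CPM (5.63 to 7.73) against 22.9 CPM (21.4 to 24.5), Cdkn1a at 24.7 against 72.7 CPM, Bax at 264 against 428 CPM and Fas at 10.2 against 17.7 CPM, while Btg2 was higher, at 132 against 84.4 CPM. The median of 17 measured targets was -0.50 (-0.69 to -0.10), with 14 lower, but with clusters at equal weight it was -0.17 (-0.53 to -0.0096), against -0.20 for all genes. Scaled by the median of ratios, 11 of 16 were lower. Most genes were lower as counted, with a median of -0.19 over all genes, so counts of lower targets alone show no shift of the list. For the 10 that had not been seen before the list was drawn up, the median was -0.26 (-0.55 to 0.27), at percentile 7.58 of random lists, with 8 lower (5 of 9, with a median of -0.058, when scaled by the median of ratios), and within clusters those genes lay below all genes in 1 of 5. Aen, Zmat3 and Trp53inp1 were farthest from 0 among them, at -0.62, -0.55 and -0.51, the last at 0.038 with thinned cells.

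The donor cells were sorted by congenic forms of CD90, encoded by Thy1, or CD45, encoded by Ptprc. Thy1 was at 390 CPM in PSGL-1-/- and 720 CPM in WT T cells, and Ptprc at 412 and 326 CPM. Phlda3, Btg2 and Ctse lie 2.30, 3.99 and 6.42 Mb from Ptprc on chromosome 1, Cd3g and Ubash3b lie 0.926 and 3.03 Mb from Thy1 on chromosome 9, and Rplp0 lies 1.74 Mb from Selplg on chromosome 5. Whether a stretch of donor strain DNA around the sorted marker accounts for the levels of Ctse, Thy1 or their neighbours, and not the loss of PSGL-1, was not tested. Gm8730 was at 4420 CPM in PSGL-1-/- and 423 CPM in WT T cells. Cell barcodes shared by the libraries numbered 36.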
